A study of Ananas comosus with 9 samples.

How the data were processed

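Peels of pineapple fruit were represented by 9 RNA-seq libraries, 3 from each of the fruit ages 60, 90 and 120 DAF (days after flowering), per the labels. Per the labels' protocols, poly(A) RNA was captured with oligo-dT beads, fragmented, copied into paired-end libraries and sequenced on an Illumina NovaSeq instrument. The labels do not say that the 3 libraries of an age came from separate fruits or plants, so p-values measure only the spread between these samples, which may be technical.

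The deposited table holds whole-number read counts per gene, per the file headers, for 26730 gene models on 25 contigs. It also holds the authors' FPKM values (fragments per kilobase, scaled to library depth), per the file headers, in which all 65846 values at count 0 are written as 0.0001. Per the submitters' processing notes, Bowtie 0.12.2, HISAT2 2.0 and StringTie 1.3.0 were used. Their roles, the genome build and the strand setting are not given in the sources used here. Contig numbers and positions below are those of the deposited table. A product description was present for 2353 genes, a KEGG ortholog for 7631, an EC number for 4633 and a GO term for 15775. The counting method could split reads between near-identical copies, so genes of multigene families are uncertain to that extent. No gene of the RefSeq table at hand could be matched to these identifiers, and it was not used here.

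Tests ran on the counts as deposited. Genes with at least 1 FPKM in at least 3 libraries were kept (16791), and 1 edgeR quasi-likelihood model with TMM scaling was fitted to all 9 libraries, with 6 residual degrees of freedom. The 3 pairs of ages were compared, and a 4th contrast asked whether the change from 90 to 120 DAF differed from the change from 60 to 90 DAF. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and 0.05 was the threshold. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Fold changes carry the TMM scaling, while FPKM values in the text and figures do not, so ratios of printed FPKM values differ from the folds. The TMM factors ran from 0.849 to 0.911 at 120 DAF, 0.973 to 1.148 at 90 DAF and 1.027 to 1.085 at 60 DAF. The design fixed before the data were examined had assumed log2(FPKM + 1) values tested with limma. It named this edgeR test in case counts were found instead, and the table held both. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

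The groups, the contrasts, the themes of 32 gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The themes had been written as description patterns. Because few genes carried descriptions, members were assigned by KEGG ortholog, EC and GO codes, which were written after the table was opened and before any test. With a minimum of 3 tested members, 27 lists could be tested and 5 could not. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. KEGG pathways with 10 to 300 tested genes (117) were tested with both forms of camera and not with fry.

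By the rule for named genes, each comparison takes the 8 largest changes each way among called genes without overlap between the groups, with a mean of at least 5 FPKM and a product name. It also takes up to 4 called members of each list with a mean of at least 1 FPKM, and the most highly expressed gene of each enzyme step of the phenylpropanoid and flavonoid lists, called or not. A full EC number served as product name where the description was empty. The rule names 211 called and 21 uncalled gene and comparison pairs. All of them enter the counts of results that held under the alternatives. The text prints only some of them, and that choice was made after their values were seen. Genes outside the rule are said to have been chosen after their values were seen.

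For a gene at count 0 in every library of an age, the fold is a lower bound against a floor of 3 counts over that age. Such floors cover counting error only. Library totals ran from 35038248 to 52937826 counts. In data simulated from these libraries with 16791 genes, the edgeR test recovered 40% of the genes changed 4-fold for 90 against 60 DAF. The shares were 46.25% for 120 against 90 DAF and 50% for 120 against 60 DAF. These runs called 67, 75 and 85 genes, against 132, 2915 and 1590 in the data. The shares therefore do not show how many changes of that size were missed in the data.

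Alternatives chosen beforehand were another pseudocount, no filter or a stricter filter on low values, median-ratio scaling, quantile normalization, the replicate number as a block, limma arrayWeights, only the 2 compared groups in the fit, and each library left out in turn. The pseudocount of 0.1, quantile normalization and arrayWeights used limma on log2 FPKM, so they changed the test and the unit too. The limma arrayWeights fit stopped before it converged. It weighted 90 DAF replicate 1 at 5.89, against 0.31 and 0.23 for replicates 2 and 3. After the data were seen, limma on log2(FPKM + 1), gene-by-gene arrayWeights, DESeq2, total count scaling, and the removal of 90 DAF replicate 1 together with 120 DAF replicate 2 were added. The first of these was the test that the design had assumed for FPKM values. Anthocyanidin synthase was not analysed here.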

Results

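The peel of pineapple (Ananas comosus) was profiled at 60, 90 and 120 DAF with 3 libraries per age, in a series on anthocyanins and the loss of peel colour as the fruit matures. Total counts were 38899506, 35038248 and 35116298 at 60 DAF, 52937826, 44448502 and 35388467 at 90 DAF, and 39160824, 44581579 and 44898100 at 120 DAF. The 10 largest genes took 7.06, 7.76 and 8.71% of counts at 60 DAF, 6.07, 6.04 and 5.04% at 90 DAF, and 13.1, 11.4 and 9.85% at 120 DAF. Among them Aco013999, annotated as a serine-type endopeptidase inhibitor and chosen after its values were seen, took 1.08 to 2.52% at 60 and 90 DAF and 2.65 to 5.25% at 120 DAF. The first principal component (42.5% of the variance) placed the 3 libraries of 120 DAF apart from the other 6. Replicates spread most at 90 DAF, with a common biological coefficient of variation of 0.501 against 0.354 at 60 DAF and 0.432 at 120 DAF. Among the 90 DAF libraries the Pearson correlation of log2 counts, scaled to depth, was 0.936 for replicates 1 and 2. It was 0.911 for replicates 1 and 3 and 0.871 for replicates 2 and 3. Replicate 1 correlated at 0.896 to 0.907 with the libraries of 60 DAF. Replicate 3 thus stood apart by correlation and on component 2 (96.7 against 34.0 and 2.64). On component 1 replicate 2 did (-99.3 against -49.1 and -55.1).

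**Figure D1:**
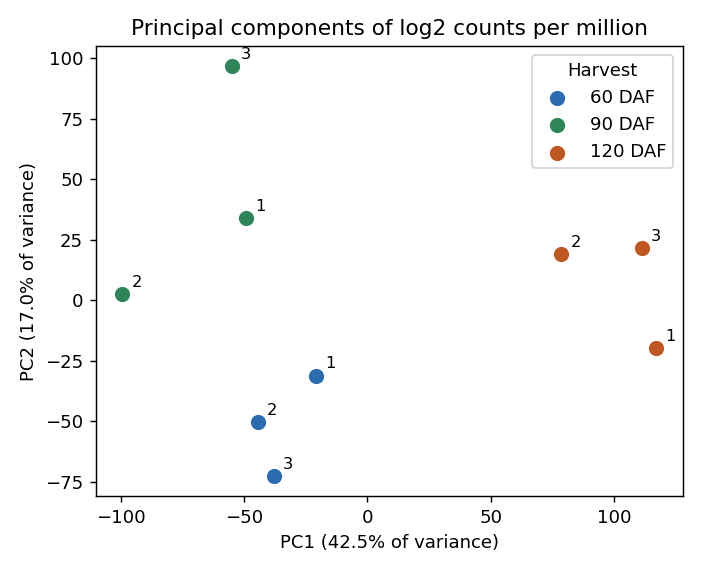
Principal components of the 9 libraries, with component 1 (42.5% of the variance) on the x axis and component 2 (17.0%) on the y axis. Each point is a library, coloured by days after flowering and labelled with its replicate number, and the 3 libraries of 120 DAF lie apart from the others on component 1.

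Between 60 and 90 DAF edgeR called 132 of 16791 genes. Among those that rose, the light-harvesting chlorophyll a/b-binding protein gene Aco003394 went from 7.71 ± 1.63 to 217 ± 246 FPKM (SD, n = 3), a log2 fold change of 4.77 ± 0.80 (SE, edgeR, adjusted p = 0.0433). Sucrose synthase Aco006349, which cleaves sucrose in sink tissues, went from 619 ± 108 to 98.7 ± 52.5 FPKM, 6.48-fold lower (adjusted p = 0.0384). Phosphoenolpyruvate carboxylase Aco010025, which fixes bicarbonate into organic acids, went from 854 ± 201 to 142 ± 76.2 FPKM (log2 fold change -2.64 ± 0.41, adjusted p = 0.0384). The Aux/IAA auxin repressor gene Aco005634 was 15.4-fold lower at 90 DAF (-3.95 ± 0.35, adjusted p = 0.0230).

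Other genes that rose from 60 to 90 DAF were PnsB5 (Aco004218), a subunit of the chloroplast NDH complex, from 3.43 to 106 ± 109 FPKM, and chloroplastic thioredoxin-like 1-2 (Aco004156), from 4.33 to 28.9 ± 11.3 FPKM. The wax alkane enzyme gene Aco008234 (EC 4.1.99.5) and the proton pump gene Aco002130 (EC 3.6.3.6) were 7.10-fold and 3.28-fold higher. The ethylene receptor gene Aco004737 had 0 counts at 60 DAF and 413 at 90 DAF, at least 110.5-fold higher. Starch synthase Aco010848 (-2.24 ± 0.22), chloroplastic phosphoglucomutase Aco017741 (-1.89 ± 0.19), aconitase Aco009034 (-4.64 ± 0.65) and chitinase Aco011824 (-2.63 ± 0.41) fell, as did MAP kinase 16 (Aco000644, -2.60 ± 0.41) and the zeaxanthin epoxidase gene Aco010449 (-1.86 ± 0.33). Their adjusted p-values by edgeR lay between 0.0230 and 0.0497.

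Of the 23 tested genes of flavonoid and anthocyanin synthesis none was called by edgeR from 60 to 90 DAF. Chalcone synthase Aco016200, the entry enzyme of the flavonoid pathway, stood at 89.5 ± 30.9 and 67.9 ± 55.03 FPKM (-0.41 ± 1.08, edgeR adjusted p = 0.891). Its adjusted p was 0.00877 with limma arrayWeights, whose fit did not converge, within 0.00877 to 0.996 over all alternatives. Dihydroflavonol 4-reductase Aco006769 stood at 128 ± 90.4 and 166 ± 150 FPKM (0.36 ± 0.77, adjusted p = 0.859). Anthocyanidin 3-O-glucosyltransferase Aco012126 (0.62 ± 0.60, adjusted p = 0.659), chalcone isomerase Aco012554 (0.35 ± 0.23, adjusted p = 0.480) and phenylalanine ammonia-lyase Aco013943 (1.26 ± 0.68, adjusted p = 0.398) were not called either. The same held for flavonoid 3',5'-hydroxylase Aco017169 (0.95 ± 0.78, adjusted p = 0.594, and 0.0493 with arrayWeights, within 0.0493 to 0.789 over all alternatives). In the flavonoid list 0 of 23 tested members passed edgeR, and 0 when adjusted over the list alone (camera adjusted p = 0.279). There were 3 higher and 1 lower at an unadjusted p under 0.05, 1 higher and 1 lower by DESeq2 and 0 by limma on log2(FPKM + 1). Without 90 DAF replicate 2 the list median of 0.36 became -0.20. In the phenylpropanoid list 0 of 14 passed, and 1 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.279), as also by DESeq2 and at an unadjusted p under 0.05, against 0 by limma on log2(FPKM + 1).

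The light-reaction list was higher at 90 than at 60 DAF, with 1 of 53 members called and 11 when adjusted over the list alone (median log2 fold change 1.82, camera adjusted p = 1.63e-10). The same test gave an adjusted p = 0.591 with an estimated correlation, within 2.79e-21 to 0.591 over all alternatives. For Aco003394, 90 DAF replicate 2 stood apart, at 501 FPKM against 94.1 and 56.0 in the other libraries of that age. Without that library the list median was 0.52 and 3 members were called, and 0 were called without 90 DAF replicate 1, any library of 60 DAF or any library of 120 DAF. In the auxin list 1 of 50 members fell, and 1 when adjusted over the list alone (camera adjusted p = 0.0279; adjusted p = 0.578 with an estimated correlation, 0.00347 to 0.578 over all alternatives). The camera adjusted p was 0.0534 without 60 DAF replicate 3 and 0.0970 without 90 DAF replicate 1. The cell wall list was higher with 0 of 102 members called by edgeR and 0 when adjusted over the list alone, against 18 higher and 7 lower at an unadjusted p under 0.05, 10 and 4 by DESeq2 and 3 higher by limma on log2(FPKM + 1) (median 0.32, camera adjusted p = 0.0279). This list had an adjusted p = 0.518 with an estimated correlation, within 0.00363 to 0.518 over all alternatives. Without 60 DAF replicate 1 or 90 DAF replicate 2 its camera adjusted p was 0.158 or 0.0823.

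In total 132 of 16791 genes changed from 60 to 90 DAF by edgeR, 54 higher and 78 lower, against 2845 genes at an unadjusted p under 0.05. All 19 called genes that the rule names for this comparison lost their call without 60 DAF replicate 2, without 60 DAF replicate 3 and without 90 DAF replicate 1, where edgeR called 0, 0 and 5 genes in all against 2053 and 2003 at an unadjusted p under 0.05 for the first and second. The count was 3 without 60 DAF replicate 1, 276 and 27 without 90 DAF replicates 2 and 3, and 38 and 1 without 120 DAF replicates 1 and 3. With all libraries DESeq2 called 1437 genes and limma on log2(FPKM + 1) 293.

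Between 90 and 120 DAF 11 of 23 tested genes of flavonoid and anthocyanin synthesis fell. Chalcone synthase Aco016200 (contig 18, 10496610 to 10501469) went from 67.9 ± 55.03 to 0.263 ± 0.455 FPKM (SD, n = 3), a log2 fold change of -7.62 ± 1.48 (SE, edgeR, adjusted p = 0.0132), and 0.0532 with only these ages in the fit (6.84e-05 to 0.0532 over all alternatives). The flavanone 3-hydroxylase gene Aco018609 (EC 1.14.11.9) had 1870 counts at 90 DAF and 0 at 120 DAF, at least 486-fold lower, and the glutathione transferase gene Aco018386 (EC 2.5.1.18), of an enzyme class that includes flavonoid carriers, had 7514 and 0, at least 1953-fold lower. Flavonoid 3',5'-hydroxylase Aco017169, which sets the hydroxylation of the anthocyanidin, fell from 5.92 ± 0.614 to 0.0367 ± 0.0635 FPKM (-6.90 ± 1.06, adjusted p = 0.00666). Anthocyanidin 3-O-glucosyltransferase Aco012126, which makes the stable pigment, fell from 77.5 ± 67.3 to 2.94 ± 0.754 FPKM (-4.40 ± 0.70, adjusted p = 0.00734).

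Chalcone isomerase Aco012554 fell less, from 277 ± 39.9 to 120 ± 30.01 FPKM (-0.92 ± 0.23, edgeR adjusted p = 0.0298). Its call ended without 60 DAF replicate 3, 90 DAF replicate 1 or 2, or 120 DAF replicate 1 or 3, with adjusted p from 0.0530 to 0.104 (6.61e-04 to 0.104 over all alternatives). Dihydroflavonol 4-reductase Aco006769 missed the threshold, at 166 ± 150 and 19.3 ± 13.6 FPKM (-2.79 ± 0.82, adjusted p = 0.0504, 0.00144 to 0.141 over all alternatives). So did flavanone 3-hydroxylase Aco027895 (-0.70 ± 0.71, adjusted p = 0.539) and flavonoid 3'-hydroxylase Aco003857 (-0.29 ± 0.47, adjusted p = 0.718, and 0.03004 with arrayWeights, within 0.03004 to 0.951 over all alternatives). In the flavonoid list 11 of 23 members fell, against 13 that fell and 1 that rose when adjusted over the list alone (median -1.29, camera adjusted p = 1.84e-06). The list then had an adjusted p = 0.322 with an estimated correlation, within 6.56e-09 to 0.322 over all alternatives. Without 60 DAF replicate 3, 90 DAF replicate 2, 120 DAF replicate 1 or 120 DAF replicate 3 it was 7 that fell, and without the last of these the median was -0.81. Of the flavonol and proanthocyanidin branches 2 of 9 fell, and 2 when adjusted over the list alone (camera adjusted p = 0.646), among them flavonol synthase Aco002683 (-2.57 ± 0.60, adjusted p = 0.0236). That call ended without 90 DAF replicate 2 (0.0534), 120 DAF replicate 1 (0.0539) or 120 DAF replicate 2 (0.0674), within 1.68e-04 to 0.0876 over all alternatives.

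Upstream of the flavonoid branch some genes rose instead. Phenylalanine ammonia-lyase Aco020618, which opens the phenylpropanoid pathway, went from 0.751 ± 0.190 to 22.6 ± 11.8 FPKM (5.22 ± 0.50, edgeR adjusted p = 0.00196), and 4-coumarate-CoA ligase Aco019975 from 36.9 ± 12.5 to 116 ± 7.71 FPKM (1.96 ± 0.42, adjusted p = 0.0181). The latter call ended without 90 DAF replicate 2 (0.0539), 120 DAF replicate 1 (0.0543) or 120 DAF replicate 3 (0.0526), within 1.08e-04 to 0.0543 over all alternatives. The more highly expressed phenylalanine ammonia-lyase Aco013943 was not called (135 ± 128 and 89.9 ± 21.01 FPKM, adjusted p = 0.748). In the phenylpropanoid list 3 of 14 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.189). In the lignin list 10 of 44 rose and 7 fell, against 11 and 8 when adjusted over the list alone (camera adjusted p = 0.430). Under total count scaling 6 rose and 8 fell. Its members moved both ways: the cinnamyl-alcohol dehydrogenase gene Aco006590 (EC 1.1.1.195) was 53.4-fold higher at 410 ± 318 FPKM, and the hydroxycinnamoyltransferase gene Aco002136 was 115-fold lower. Of the laccases 2 of 5 fell, and 2 when adjusted over the list alone (camera adjusted p = 0.430), among them Aco002864 (-2.60 ± 0.44, adjusted p = 0.00866). Of the class III peroxidases 2 of 45 rose and 8 fell, against 4 and 12 when adjusted over the list alone (camera adjusted p = 0.00514; adjusted p = 0.310 with an estimated correlation, 7.30e-04 to 0.310 over all alternatives), with Aco020332 199-fold lower. Without 120 DAF replicate 1 it was 4 that fell and 0 by edgeR that rose, and 1 rose without 90 DAF replicate 2 or 120 DAF replicate 3.

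**Figure D2:**
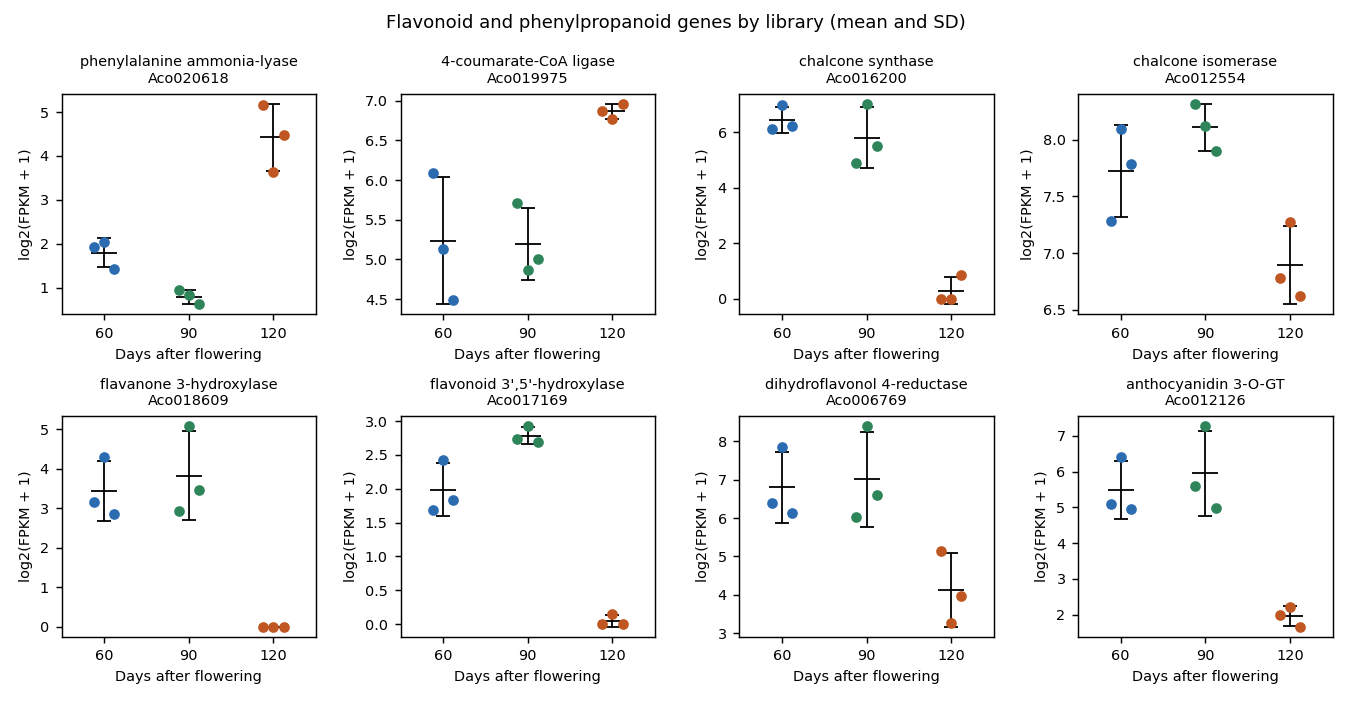
Expression of 8 phenylpropanoid and flavonoid genes as log2(FPKM + 1) on the y axis, which differs between panels, against days after flowering on the x axis. The flavanone 3-hydroxylase shown is Aco018609, and the more highly expressed Aco027895, which was not called, is not shown. Points are libraries and bars show mean and SD (n = 3); chalcone synthase Aco016200 fell to 0.263 FPKM at 120 DAF while phenylalanine ammonia-lyase Aco020618 rose to 22.6 FPKM.

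Many genes of the light reactions also fell between 90 and 120 DAF. The light-harvesting gene Aco003394 went from 217 ± 246 to 0.661 ± 0.133 FPKM (-7.99 ± 0.94, edgeR adjusted p = 0.00303), and the photosystem II 22 kDa protein gene Aco017705 was 683-fold lower. In the light-reaction list 33 of 53 members fell and 2 rose, against 44 and 2 when adjusted over the list alone (median -4.08, camera adjusted p = 2.57e-15; adjusted p = 0.452 with an estimated correlation, 2.76e-23 to 0.452 over all alternatives), including 12 of 18 light-harvesting proteins and 8 of 11 photosystem I subunits. All 4 Calvin cycle genes fell, also when adjusted over the list alone (median -6.29, camera adjusted p = 9.65e-04; adjusted p = 0.399 with an estimated correlation, 1.01e-07 to 0.399 over all alternatives), among them sedoheptulose-bisphosphatase Aco014119 (-7.81 ± 1.44, adjusted p = 0.0116) and phosphoribulokinase Aco017282 (-7.03 ± 1.33, adjusted p = 0.0124). Without 120 DAF replicate 1 their adjusted p-values were 0.0502 and 0.0530 (ranges over all alternatives 1.91e-12 to 0.0502 and 9.46e-04 to 0.0530). At 90 DAF replicate 2 carried most of these transcripts, with Aco014119 at 298 FPKM against 34.1 and 12.2, and without it the light-reaction median was -2.55 with 28 members lower. The Calvin cycle median was then -3.96. Without 120 DAF replicate 1 or 3 it was 16 or 21 light-reaction members that fell, and 1 Calvin cycle gene without 120 DAF replicate 1. With 90 DAF replicate 1 and 120 DAF replicate 2 both left out, 18 light-reaction members fell.

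Of the chlorophyll synthesis genes 11 of 32 fell, and 2 of chlorophyll breakdown rose. Protochlorophyllide reductase Aco007648, the light-driven step of chlorophyll synthesis, went from 168 ± 143 to 2.15 ± 0.830 FPKM (-5.95 ± 0.70, edgeR adjusted p = 0.00303), and magnesium chelatase subunit H Aco020178 was 17.7-fold lower (adjusted p = 0.0121). In the chlorophyll synthesis list 11 of 32 fell and 1 rose, against 15 and 1 when adjusted over the list alone (median -1.02, camera adjusted p = 2.49e-04). That call had an adjusted p = 0.536 with an estimated correlation, within 1.10e-06 to 0.536 over all alternatives. Without 60 DAF replicate 2 or 3 it was 6 or 7 that fell, and 5 without any library of 120 DAF. Without 90 DAF replicate 2 the median was -0.66. Chlorophyll b reductase Aco000337 was 3.29-fold higher at 147 ± 40.4 FPKM (adjusted p = 0.00563), and the magnesium dechelatase STAY-GREEN gene Aco013139 was 4.45-fold higher at 393 ± 139 FPKM (adjusted p = 0.0373). The Aco013139 call ended without 60 DAF replicate 3, 90 DAF replicate 1 or 3, or any library of 120 DAF, with adjusted p from 0.0530 to 0.114 (0.00141 to 0.114 over all alternatives). In the breakdown list 2 of 9 rose and 1 fell, against 3 and 2 when adjusted over the list alone (camera adjusted p = 0.328).

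Phytoene synthase Aco005022, the entry step of carotenoid synthesis, rose from 10.3 ± 6.15 to 39.7 ± 1.498 FPKM (2.27 ± 0.35, edgeR adjusted p = 0.00714). Lycopene epsilon-cyclase Aco005888 was 19.7-fold lower (adjusted p = 0.0117, and 0.0521 without 120 DAF replicate 1, within 4.95e-08 to 0.0521 over all alternatives). The 9-cis-epoxycarotenoid dioxygenase gene Aco017051, of abscisic acid synthesis, was 38.5-fold lower (adjusted p = 0.0146, and 0.0613 without 120 DAF replicate 1, within 1.43e-08 to 0.0613 over all alternatives). In the carotenoid list 3 of 24 rose and 7 fell, against 3 and 8 when adjusted over the list alone (camera adjusted p = 0.999), with a median of 0.23, a mean of -0.24 and a median of -0.08 under total count scaling. Of the carotenoid cleavage list 1 of 6 fell, and 1 when adjusted over the list alone (camera adjusted p = 0.564). Of the abscisic acid signalling list 4 of 25 rose and 3 fell, against 5 and 4 when adjusted over the list alone (camera adjusted p = 0.705), with a median of 0.06, a mean of -0.49 and a test pointing up. All 3 that fell were receptor genes, Aco002505 from 93.0 ± 44.5 to 1.69 ± 1.15 FPKM among them.

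**Figure D3:**
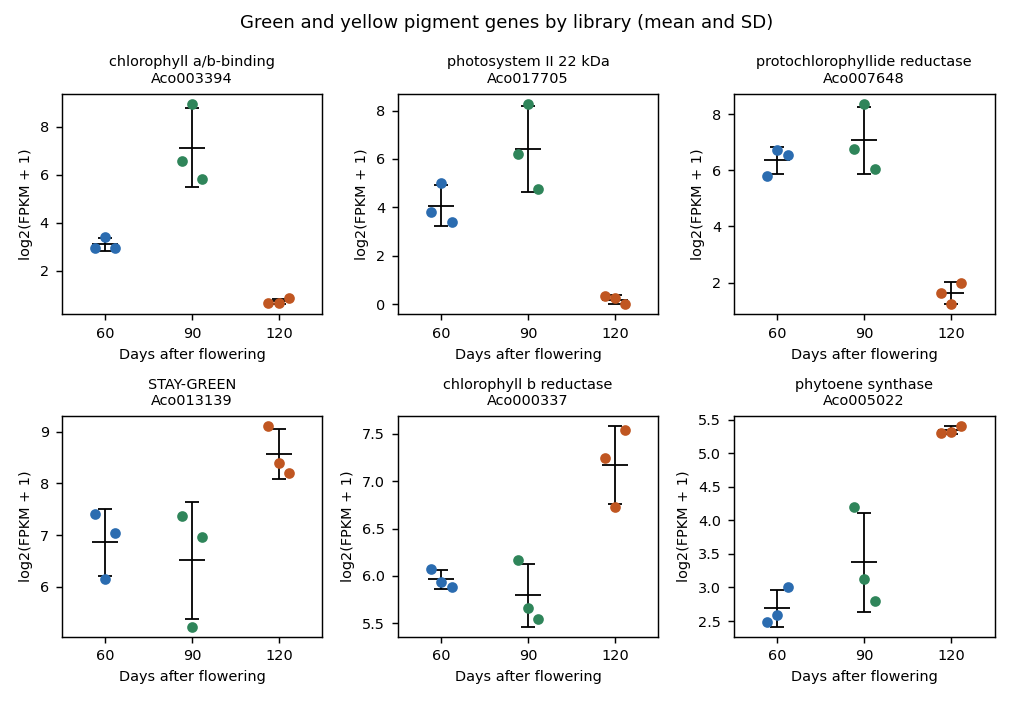
Expression of 6 chlorophyll and carotenoid genes as log2(FPKM + 1) on the y axis, which differs between panels, against days after flowering on the x axis. Points are libraries and bars show mean and SD (n = 3); protochlorophyllide reductase Aco007648 fell to 2.15 FPKM at 120 DAF and phytoene synthase Aco005022 rose to 39.7 FPKM.

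Several wall and sugar genes changed in the same interval. The polygalacturonase gene Aco012764, of pectin breakdown, rose from 1.39 ± 1.53 to 401 ± 247 FPKM, 364-fold (8.51 ± 1.09, edgeR adjusted p = 0.00368), and pectinesterase Aco019529 fell from 47.7 ± 34.3 to 0.196 ± 0.340 FPKM (-7.54 ± 1.26, adjusted p = 0.00844). In the cell wall list 27 of 102 fell and 6 rose, against 30 and 7 when adjusted over the list alone (median -0.65, camera adjusted p = 7.27e-05). Camera gave an adjusted p = 0.243 with an estimated correlation, within 2.10e-06 to 0.243 over all alternatives. The 6 that rose became 2 without 120 DAF replicate 1 and 3 without 60 DAF replicate 2 or 120 DAF replicate 3. Sucrose-phosphate synthase Aco017378, which makes sucrose, rose from 3.69 ± 3.45 to 98.4 ± 28.6 FPKM (adjusted p = 0.0101, and 0.0619 with 90 DAF replicate 1 and 120 DAF replicate 2 both left out, within 3.48e-10 to 0.0619 over all alternatives). Sucrose synthase Aco009508 fell from 238 ± 55.1 to 12.1 ± 8.52 FPKM (-4.04 ± 0.53, adjusted p = 0.00383), and hexokinase Aco005297 was 6.33-fold higher (adjusted p = 0.00914). In the sucrose list 11 of 46 rose and 4 fell, against 13 and 7 when adjusted over the list alone (camera adjusted p = 0.146), and under total count scaling 6 rose and 7 fell. In the organic acid list 11 of 37 rose and 1 fell, against 12 and 1 when adjusted over the list alone (median 0.36, camera adjusted p = 0.00138; adjusted p = 0.243 with an estimated correlation, 7.29e-04 to 0.243 over all alternatives), and under total count scaling 3 rose and 2 fell. Without a single library 5 to 11 rose, with 5 without 120 DAF replicate 1, 6 without 60 DAF replicate 2 or 3 or 120 DAF replicate 3, and 7 without 90 DAF replicate 3 or 120 DAF replicate 2. Phosphoenolpyruvate carboxylase Aco010025 was 4.36-fold higher (adjusted p = 0.0124) and aconitase Aco014852 2.31-fold higher (adjusted p = 0.0295). The Aco014852 call ended without 60 DAF replicate 2 or 3, 90 DAF replicate 3 or any library of 120 DAF, with adjusted p from 0.0510 to 0.0785 (0.00146 to 0.135 over all alternatives).

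**Figure D4:**
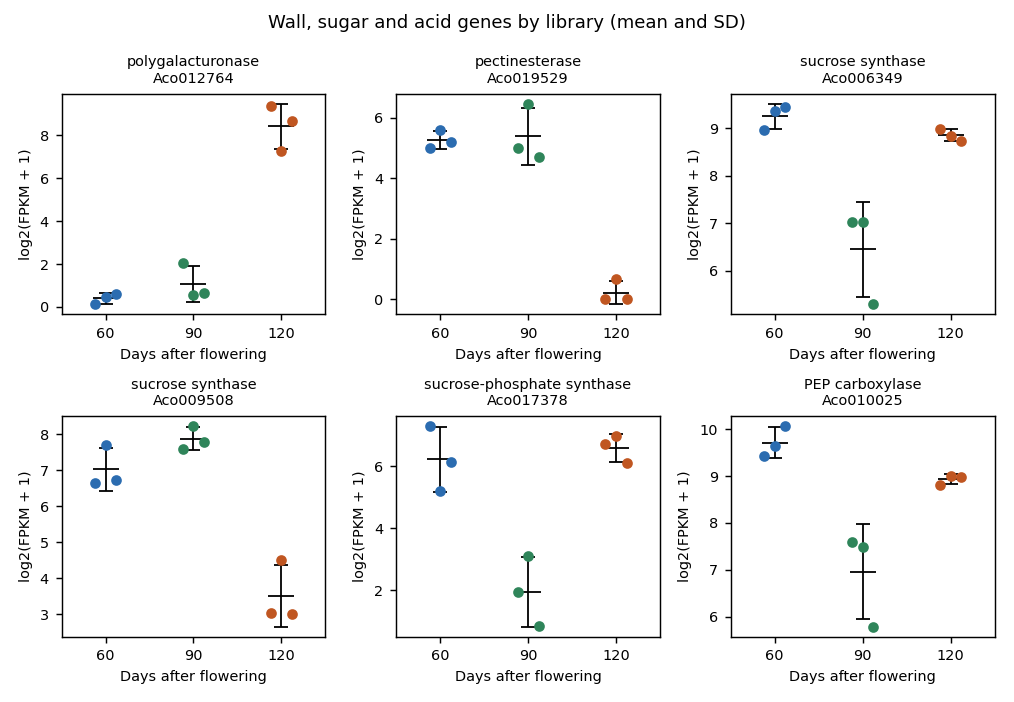
Expression of 6 wall, sucrose and acid metabolism genes as log2(FPKM + 1) on the y axis, which differs between panels, against days after flowering on the x axis. Points are libraries and bars show mean and SD (n = 3); polygalacturonase Aco012764 rose to 401 FPKM at 120 DAF and sucrose synthase Aco006349 was lowest at 90 DAF with 98.7 FPKM.

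Among other large changes to 120 DAF, the methyltransferase gene Aco030461 (EC 2.1.1.240) rose from 1.05 ± 0.9999 to 1011 ± 505 FPKM (10.16 ± 1.14, edgeR adjusted p = 0.00276), and the GH3 auxin-conjugating enzyme gene Aco012374 from 0.392 to 14.5 ± 8.60 FPKM (adjusted p = 0.0169). The latter was at 0.0501 with only these ages in the fit and at 0.0696 with 90 DAF replicate 1 and 120 DAF replicate 2 both left out, within 3.28e-07 to 0.0696 over all alternatives. The Aux/IAA gene Aco005634 rose 32.9-fold (adjusted p = 0.00153). In the auxin list 3 of 50 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.661). Of the papain-like proteases, the family of the bromelains, 1 of 8 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.894), with a median of 0.17, a mean of -0.13 and a median of -0.13 under total count scaling. Aco011478 rose from 257 ± 64.3 to 676 ± 272 FPKM and Aco004356 fell from 1390 ± 263 to 314 ± 113 FPKM, although the model of the latter spans 2467915 to 2571943 on contig 6 and can take reads of neighbours. Of the cytosolic ribosomal protein genes 16 of 208 rose and 4 fell, against 1 and 0 when adjusted over the list alone (median 0.24, camera adjusted p = 0.00164). The same test gave an adjusted p = 0.718 with an estimated correlation, within 4.41e-06 to 0.931 over all alternatives. Without 90 DAF replicate 1 and 2 in turn the median was 0.38 and 0.10, and without the latter the camera adjusted p was 0.244 (4.41e-06 to 0.931 over all alternatives), and under total count scaling 2 rose and 11 fell. Without a single library of 60 DAF 5 to 8 rose, 7 without 90 DAF replicate 3, and 1, 5 and 3 without 120 DAF replicates 1, 2 and 3. The 4 that fell became 2 without 60 DAF replicate 3 or 120 DAF replicate 2, 7 without 90 DAF replicate 3 and 0 by edgeR without 120 DAF replicate 1 or 3.

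In total 2915 genes changed from 90 to 120 DAF by edgeR, 1375 higher and 1540 lower. Under total count scaling the split was 649 higher and 2565 lower and under limma on log2(FPKM + 1) it was 713 and 2468, with the median of all genes at -0.32 and -0.26 on the log2 scale against -0.03 under TMM. The count was 1094 without 120 DAF replicate 1 and 1419 without 120 DAF replicate 3, and 50 of the 105 called genes that the rule names lost their call without at least 1 library.

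Over the whole period from 60 to 120 DAF, 8 of 23 tested genes of flavonoid and anthocyanin synthesis fell. Chalcone synthase Aco016200 had a log2 fold change of -8.03 ± 1.499 (SE, n = 3, edgeR adjusted p = 0.0188). Flavanone 3-hydroxylase Aco018609 was at least 329-fold lower and glutathione transferase Aco018386 at least 2001-fold lower. Chalcone isomerase Aco012547 went from 112 ± 23.3 to 2.47 ± 1.91 FPKM (-5.23 ± 0.78, adjusted p = 0.00945), anthocyanidin 3-O-glucosyltransferase Aco012126 from 49.3 ± 30.5 to 2.94 ± 0.754 FPKM (adjusted p = 0.0162) and flavonoid 3',5'-hydroxylase Aco017169 from 3.06 ± 1.16 to 0.0367 FPKM (adjusted p = 0.0146). Dihydroflavonol 4-reductase Aco006769 was not called (-2.43 ± 0.81, adjusted p = 0.0970, 0.00890 to 0.285 over all alternatives, with 5 of 22 past the threshold). The more highly expressed chalcone isomerase Aco012554 was not called either (-0.57 ± 0.23, adjusted p = 0.155, 0.00463 to 0.432 over all alternatives, with 2 past the threshold). The more highly expressed flavanone 3-hydroxylase Aco027895 (0.08 ± 0.71, adjusted p = 0.958) was not called. Flavonoid 3'-hydroxylase Aco003857 (-0.25 ± 0.47, adjusted p = 0.785) was not called either. Leaving out 60 DAF replicate 2 gave adjusted p-values of 0.0589 for Aco016200, 0.0501 for Aco012126 and 0.0505 for Aco017169. Leaving out 120 DAF replicate 1 gave 0.0538 for Aco016200 and 0.0648 for Aco012126, leaving out 60 DAF replicate 3 gave 0.0524 for Aco016200, and leaving out 120 DAF replicate 3 gave 0.0622 for Aco012126. Over all alternatives these genes ranged from 6.50e-05 to 0.0589, 4.36e-08 to 0.0648 and 7.82e-13 to 0.0505. In the flavonoid list 8 of 23 fell, against 10 that fell and 1 that rose when adjusted over the list alone (median -0.70, camera adjusted p = 6.57e-06). This list had an adjusted p = 0.377 with an estimated correlation, within 2.39e-08 to 0.377 over all alternatives. Without 60 DAF replicate 2 or 120 DAF replicate 1 it was 4 or 5 that fell.

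Phenylalanine ammonia-lyase Aco020618 was 10.9-fold higher at 120 than at 60 DAF (edgeR adjusted p = 0.00715), and in the phenylpropanoid list 3 of 14 rose, also when adjusted over the list alone (camera adjusted p = 0.00580). The list then had an adjusted p = 0.446 with an estimated correlation, within 0.00162 to 0.446 over all alternatives. In the chlorophyll breakdown list 3 of 9 rose and 5 when adjusted over the list alone (median 1.27, camera adjusted p = 0.00580; adjusted p = 0.233 with an estimated correlation, 0.00180 to 0.233 over all alternatives), with chlorophyll b reductase Aco000337 2.93-fold and pheophorbide a oxygenase Aco022956 2.42-fold higher. In the chlorophyll synthesis list 3 of 32 fell and 1 rose, against 4 and 1 when adjusted over the list alone (camera adjusted p = 0.0105; adjusted p = 0.559 with an estimated correlation, 0.001003 to 0.559 over all alternatives), with protochlorophyllide reductase Aco007648 31.6-fold lower. In the light-reaction list 9 of 53 fell and 2 rose, against 19 and 2 when adjusted over the list alone (median -1.73, camera adjusted p = 2.50e-07). That call had an adjusted p = 0.495 with an estimated correlation, within 1.22e-13 to 0.495 over all alternatives. Without a single library of 60 or 120 DAF 1 to 4 light-reaction members fell, and without 90 DAF replicates 2 and 3 it was 23 and 15. The 2 that rose became 1 without any library of 60 DAF, 90 DAF replicate 1, or 120 DAF replicate 1 or 3. Of 4 Calvin cycle genes 3 fell, and 4 when adjusted over the list alone (camera adjusted p = 2.95e-04; adjusted p = 0.381 with an estimated correlation, 7.37e-09 to 0.381 over all alternatives), and 0 by edgeR without any library of 60 or 120 DAF. Without 90 DAF replicates 2 and 3 and 120 DAF replicate 3 it was 11, 5 and 1 of the chlorophyll synthesis list that fell, and without 120 DAF replicate 2 that list had a camera adjusted p of 0.0585. Of the breakdown list 1 rose without 60 DAF replicate 1 or any library of 120 DAF, 0 by edgeR without 60 DAF replicate 2 or 3, and 5 without 90 DAF replicate 2. Phytoene synthase Aco005022 was 8.70-fold higher (adjusted p = 0.00581), and in the carotenoid list 2 of 24 rose and 1 fell, against 2 and 2 when adjusted over the list alone (camera adjusted p = 0.529). The call of Aco000337 ended without 60 DAF replicate 2 (0.0560) or 3 (0.0534), within 1.58e-06 to 0.0560 over all alternatives. That of Aco022956 ended without any library of 60 or 120 DAF (0.0529 to 0.104, within 3.68e-04 to 0.104 over all alternatives).

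Polygalacturonase Aco012764 was 1442-fold higher at 120 than at 60 DAF (10.49 ± 1.19, edgeR adjusted p = 0.00521), and methyltransferase Aco030461 612-fold. The terpene synthase gene Aco018929 (EC 4.2.3.104 and 4.2.3.57) rose from 7.85 ± 3.19 to 1380 ± 411 FPKM (7.76 ± 1.95, adjusted p = 0.0444), a call that ended without any library of 60 or 120 DAF (0.0672 to 0.147, within 6.36e-06 to 0.147 over all alternatives). Sucrose synthase Aco009508 fell 9.47-fold (adjusted p = 0.0109). Sucrose transporter SUC4 (Aco000269) was 2.86-fold higher (adjusted p = 0.0166), and without 60 DAF replicate 1, 60 DAF replicate 2 or 120 DAF replicate 1 its adjusted p was 0.0540, 0.0675 or 0.0589 (2.26e-05 to 0.0675 over all alternatives). In the cell wall list 16 of 102 fell and 4 rose, against 21 and 9 when adjusted over the list alone (camera adjusted p = 0.00567). Camera gave an adjusted p = 0.243 with an estimated correlation, within 2.78e-04 to 0.243 over all alternatives. In the peroxidase list 9 of 45 fell and 1 rose, against 14 and 1 when adjusted over the list alone (camera adjusted p = 2.95e-04). The same test gave an adjusted p = 0.233 with an estimated correlation, within 3.17e-05 to 0.233 over all alternatives. In the auxin list 8 of 50 fell and 1 rose, against 10 and 3 when adjusted over the list alone (camera adjusted p = 0.0113). This list had an adjusted p = 0.450 with an estimated correlation, within 0.00552 to 0.450 over all alternatives. In the ribosomal list 6 of 208 rose and 2 fell, against 2 and 1 when adjusted over the list alone (camera adjusted p = 5.61e-05; adjusted p = 0.559 with an estimated correlation, 8.71e-07 to 0.959 over all alternatives), 53 rose without 90 DAF replicate 2, 0 to 2 by edgeR without a single library of 60 DAF or 120 DAF replicate 1 or 3, and under total count scaling 3 rose and 4 fell. The 2 ribosomal members that fell became 6 without 90 DAF replicate 2 and 0 by edgeR without 60 DAF replicate 2 or 3 or 120 DAF replicate 3. Without a single library of 60 DAF 9 or 10 cell wall members fell, and 10 without 120 DAF replicate 1 or 3, and 2 rose without 60 DAF replicate 2. Of the peroxidases 3 to 5 fell without 60 DAF replicate 2 or 3 or 120 DAF replicate 1 or 3. The 1 peroxidase that rose became 0 by edgeR without any library of 60 or 120 DAF or 90 DAF replicate 1. Of the auxin list 0 or 1 fell by edgeR without a single library of 60 DAF or 120 DAF replicate 1 or 3, 4 without 90 DAF replicate 1 and 5 without 120 DAF replicate 2. Its 1 member that rose became 0 by edgeR without any library of 60 DAF or 120 DAF replicate 1 or 3, and 2 without 90 DAF replicate 3.

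In total 1590 genes differed between 60 and 120 DAF by edgeR, 714 higher and 876 lower at 120 DAF. The split was 381 and 1506 under total count scaling and 465 and 1602 under limma on log2(FPKM + 1), with the median of all genes at -0.29 and -0.26 on the log2 scale against -0.01 under TMM. Leaving out 60 DAF replicate 1, 2 or 3 gave 740, 392 or 447 genes, leaving out 120 DAF replicate 1 or 3 gave 491 or 585, and leaving out 90 DAF replicate 2 gave 2452. Of the 87 called genes that the rule names, 69 lost their call without at least 1 library.

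The change from 90 to 120 DAF differed from that of the earlier interval for several of these genes. The Aux/IAA gene Aco005634, at 35.7, 2.33 and 62.5 FPKM over the 3 ages, fell and then rose (difference of the log2 changes 8.99 ± 0.69, SE, n = 3 per age, edgeR adjusted p = 0.00233). Sucrose synthase Aco006349 (5.26 ± 0.74, adjusted p = 0.00898), phosphoenolpyruvate carboxylase Aco010025 (4.76 ± 0.76, adjusted p = 0.0131) and starch synthase Aco010848 (4.01 ± 0.40, adjusted p = 0.00420) had the same course. The light-harvesting gene Aco003394 had the opposite one (-12.76 ± 1.28, adjusted p = 0.00420), and for chalcone synthase Aco016200 the difference missed the threshold (-7.21 ± 1.89, adjusted p = 0.0509). In total 1521 genes changed unequally, 599 with a higher and 922 with a lower change in the later interval. That split was 360 and 1343 under total count scaling and 448 and 1077 under limma on log2(FPKM + 1), where the medians of all genes were -0.36 and -0.25. The count was 588, 662 and 549 without 60 DAF replicates 1, 2 and 3, 904 and 837 without 90 DAF replicates 1 and 2, and 731 and 786 without 120 DAF replicates 1 and 3.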

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

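The regroupings of libraries below were planned, and no test in this part was chosen after its result was seen. The changes in the 2 intervals differed for 1521 genes by the edgeR contrast between them, which is what singled this result out. Of 100 drawn regroupings of the 9 libraries, counting the real one, 1 gave as many genes, and the highest other gave 154. The other regroupings mix libraries of different ages, which adds the differences between ages to the spread. They therefore stand for no difference between ages at all, and cannot tell whether chance gives unequal changes where the ages do differ. The Aux/IAA gene Aco005634 and the starch synthase gene Aco010848 were among the genes with a lower level at 90 DAF than at both other ages.

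For the pairs of ages, 3 libraries against 3 allow 10 splits, which are too few for a share under 0.05. From 60 to 90 DAF the real split gave 132 genes and the highest other 2. From 90 to 120 DAF the values were 2915 and 5, and from 60 to 120 DAF 1590 and 2. In each case 1 of the 10 splits, the real one, gave as many genes.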

How the results depend on the processing

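The tests with limma on log2(FPKM + 1), gene-by-gene arrayWeights, DESeq2, total count scaling, and 90 DAF replicate 1 and 120 DAF replicate 2 both left out were added as alternatives only after the results were seen. The first of these had been the test assumed in the design for FPKM values. There were 13 alternatives and 9 fits with 1 library left out. Of 211 called gene and comparison pairs, 67 stayed past the threshold in every one of these settings that tested them, and 0 reversed. Some pairs, such as Aco013254 from 90 to 120 DAF, were tested in 21 settings and not in 22, since the stricter filter removed genes with low values. Of 21 uncalled pairs 6 passed in some setting and 13 reversed in some. The calls lost numbered 96 with both libraries out, 53 with the replicate block, 50 with only 2 groups fitted, 37 by limma under quantile normalization and 22 with no filter. With single libraries left out they numbered 107 without 120 DAF replicate 3, 104 without 120 DAF replicate 1, 89 and 88 without 60 DAF replicates 2 and 3, and 25 to 59 without the others. Where not said otherwise, the cause was not tested.

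From 60 to 90 DAF the edgeR count of 132 became 76 with no filter, 54 with only 2 groups fitted, 85 under total count scaling and 15 with both libraries out. It ran from 0 to 276 with single libraries left out. DESeq2 called 1437 genes and limma on log2(FPKM + 1) 293. Against that limma count, limma called 209 with a pseudocount of 0.1, 362 under quantile normalization, 4527 with arrayWeights and 1060 with gene-by-gene arrayWeights. From 90 to 120 DAF the count of 2915 became 7790 with arrayWeights, 4788 gene by gene, 1215 with 2 groups, 4658 with DESeq2 and 1577 with both libraries out, and 1094 to 3164 with single libraries out. From 60 to 120 DAF the count of 1590 became 6111, 5690, 2585, 3393 and 891 in the same order, and 392 to 2452 with single libraries out. The unequal changes (1521) became 6777 with arrayWeights, 2431 gene by gene, 3357 with DESeq2 and 769 with both libraries out, and 549 to 1493 with single libraries out. The arrayWeights fit stopped before it converged. Fewer samples and residual degrees of freedom enter the fits with 2 groups or with libraries left out. Fits with 2 groups also take the spread from those ages alone. With them 120 against 90 DAF fell to 1215 genes while 120 against 60 DAF rose to 2585, so the order of these counts depends on whether all ages share the fit.

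With the replicate number as a block, the counts were 10, 1970 and 995 for the pairs of ages and 666 for unequal changes. The labels do not say that a number pairs samples across ages. Deviations of libraries with the same number correlated between -0.339 and 0.390, against -0.3605 to 0.312 for different numbers. These ranges overlap and do not settle whether the numbers pair samples.

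Of the gene lists 3, 8 and 10 passed in the 3 comparisons with a preset correlation, and 0, 0 and 0 by camera with an estimated correlation. For KEGG pathways 6, 12 and 6 of 117 passed, and 0, 0 and 0 by camera with an estimated correlation. The flavonoid list then stood at 0.322 from 90 to 120 DAF and 0.377 from 60 to 120 DAF. Under quantile normalization 5 lists passed from 90 to 120 DAF, and the ribosomal list turned down (adjusted p = 0.931). From 60 to 90 DAF 2 to 11 lists passed with single libraries left out. Of 21 list calls, fry, which asks another question, lost 10. The flavonoid list passed it, with a fry adjusted p of 0.00919 from 90 to 120 DAF and 0.0130 from 60 to 120 DAF.

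Uncalled enzymes changed sign in some settings. For flavonoid 3'-hydroxylase Aco003857, 90 DAF vs 60 DAF, the log2 fold change of 0.04 became -0.0606 with a pseudocount of 0.1, -0.068 under quantile normalization, -0.047 with limma on log2(FPKM + 1), -0.078 with both libraries out and -0.31 to 0.43 with single libraries out. In that comparison, with arrayWeights and gene by gene, 4-coumarate-CoA ligase Aco019975 was at 0.55 and 0.42 and dihydroflavonol 4-reductase Aco006769 at -1.07 and -0.64, and 3-O-glucosyltransferase Aco012126 was at -0.20 with arrayWeights. Over single libraries these ran from -0.50 to 0.41, -0.63 to 1.08 and -0.34 to 1.23, phenylalanine ammonia-lyase Aco013943 from -0.029 to 1.66, cinnamate 4-hydroxylase Aco007124 from -0.0079 to 1.38 and flavanone 3-hydroxylase Aco027895 from -0.16 to 1.26. From 90 to 120 DAF Aco013943 was at 0.23 with arrayWeights, 0.13 gene by gene and -0.77 to 0.91 over single libraries. Aco007124 was at -0.043 with both libraries out and -0.11 to 1.26 over single libraries, where Aco003857 ran from -0.69 to 0.066 and Aco027895 from -1.18 to 0.23. From 60 to 120 DAF Aco027895 was at -0.28 with a pseudocount of 0.1, -0.034 under quantile normalization, -0.26 with limma on log2(FPKM + 1), -0.25 with arrayWeights, -0.22 gene by gene, -0.18 under total count scaling, -0.23 with both libraries out and -0.23 to 0.41 over single libraries, where Aco003857 ran from -0.50 to 0.087.

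In data simulated at this depth, with 1 spread per gene for all ages and 3 libraries an age, without varying any of them, edgeR recovered 1.25, 2.5 and 8.75% of 2-fold changes in the 3 comparisons, and 35% of unequal changes even at 16-fold. These runs called fewer genes than the data did (16 against 1521 for unequal changes), so the shares do not carry over to the data.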

Other observations

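The tests of the 3 patterns on photosynthesis, harvest hour and mixed RNA were chosen only after the results were seen, and the bounds of all 3 were made stricter after their values were seen. From 90 to 120 DAF 13 of 33 kinesin-type motor genes, which move chromosomes and vesicles, fell, and of 38 core histone genes 5 rose (2 under total count scaling). Neither subgroup was tested for enrichment. Kinesin Aco008630 went from 1.85 ± 0.263 to 0.0108 ± 0.0186 FPKM (SD, n = 3; log2 fold change -6.91 ± 0.95, edgeR adjusted p = 0.00468). In the whole cell cycle list 6 of 79 rose and 14 fell, against 8 and 17 when adjusted over the list alone (camera adjusted p = 0.560), with a median of 0.03, a mean of -0.34, and 2 and 17 under total count scaling. The WRKY factor gene Aco003674 rose from 14.2 ± 3.47 to 39.3 ± 8.75 FPKM (adjusted p = 0.00978), in a senescence list with 4 of 34 higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.667, median -0.25, mean -0.10, test up). The CYP86A-type hydroxylase gene Aco011763 rose from 0.703 ± 0.515 to 11.4 ± 4.32 FPKM (adjusted p = 0.00829), while 3 of 22 cuticle genes fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.0780). The glucan endo-1,3-beta-glucosidase gene Aco005973 fell from 6.88 ± 3.83 to 0.111 ± 0.0961 FPKM (adjusted p = 0.00885), in a defence list with 7 of 43 higher and 10 lower, against 12 and 12 when adjusted over the list alone (camera adjusted p = 0.457). Of 38 heat shock genes 2 rose and 6 fell, against 2 and 8 when adjusted over the list alone (camera adjusted p = 0.413), 4 of the latter among 13 HSP70 genes. In the ethylene list 1 of 24 rose and 4 fell, against 1 and 5 when adjusted over the list alone (camera adjusted p = 0.366). Of the pollen list 1 of 4 rose, also when adjusted over the list alone (camera adjusted p = 0.298), and it was the sucrose-phosphate synthase gene Aco017378.

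Some KEGG pathways stood higher at 120 than at 90 DAF under TMM scaling, after 2 of them had stood lower at 90 than at 60 DAF. From 90 to 120 DAF, in the proteasome pathway 31 of 71 genes rose and 2 fell (median 0.55, camera adjusted p = 9.57e-06), in oxidative phosphorylation 44 of 139 rose and 7 fell (median 0.37, adjusted p = 2.89e-04) and in the citrate cycle 15 of 58 rose and 3 fell (adjusted p = 0.00811). In brassinosteroid synthesis 6 of 16 rose and 2 fell (adjusted p = 0.0439). All 4 had an adjusted p = 0.546 with an estimated correlation. Under total count scaling 5 and 6, 17 and 9, 5 and 4, and 6 and 3 genes rose and fell. From 60 to 90 DAF oxidative phosphorylation (median -0.25, 1 rose and 6 fell, camera adjusted p = 8.12e-04) and the proteasome (median -0.17, adjusted p = 0.0223) pointed down, both with an adjusted p = 0.804 with an estimated correlation. From 60 to 120 DAF oxidative phosphorylation (median 0.11, camera adjusted p = 0.364) and the citrate cycle (0.18, 0.327) did not pass. The proteasome (median 0.36, 5 rose and 2 fell) and brassinosteroid synthesis (0.83, 6 and 0) had a camera adjusted p = 0.0184 each, and an adjusted p = 0.875 with an estimated correlation, while under total count scaling 2 and 5, and 5 and 2, rose and fell.

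In the lists not yet described, from 60 to 90 DAF, 0 members were called by edgeR for flavonols and proanthocyanidins (camera adjusted p = 0.0811; 2 higher at an unadjusted p under 0.05, 1 by DESeq2), lignin (0.446; 7 and 5; 5 and 3), laccases (0.451; 1 and 0; 1 and 0), peroxidases (0.828; 4 and 6; 3 and 3), chlorophyll synthesis (0.0783; 5 and 1; 4 and 1), chlorophyll breakdown (0.127; 2 and 0; 0 and 0) and the Calvin cycle (0.279; 1 and 0; 0 and 0). The same held for carotenoid cleavage (0.828; 1 and 1; 0 and 0), abscisic acid signalling (0.279; 3 and 4; 1 and 3), bromelains (0.368; 0 and 2; 0 and 1), senescence (0.279; 1 and 6; 0 and 2), the cell cycle (0.279; 3 and 10; 3 and 3), ribosomal proteins (0.561; 6 and 5; 5 and 2), heat shock (0.0783; 7 and 2; 5 and 1), pollen (0.279; 0 and 1; 0 and 1) and organelle transcripts (0.279; 1 and 0; 0 and 0). In both groups the pairs are members higher and lower, first at an unadjusted p under 0.05 and then by DESeq2. By limma on log2(FPKM + 1) the peroxidases had 3 higher, lignin and heat shock 1 higher each, pollen 1 lower, abscisic acid signalling 1 each way and the others of these lists 0. When adjusted over the list alone 4 rose and 1 fell for lignin, 1 rose for laccases, peroxidases and heat shock, 1 rose and 3 fell for abscisic acid signalling, 1 fell for pollen, and 0 passed by edgeR in the others. Among lists with calls, 1 of 24 fell for carotenoids (camera adjusted p = 0.279, 1 and 1 when adjusted over the list alone), 1 of 24 rose for ethylene (0.251, 1 alone), 1 of 22 rose for the cuticle (0.279, 1 alone), 1 of 46 fell for sucrose (0.446, 3 and 5 alone), 2 of 37 fell for organic acids (0.0783, 2 and 5 alone) and 1 of 43 fell for defence (0.828, 2 and 5 alone). Median, mean and test differed in sign for carotenoid cleavage (-0.07, 0.24, down), sucrose (0.00, -0.07, down), senescence (0.04, -0.06, down) and pollen (0.08, -1.06, down).

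From 90 to 120 DAF 0 of 12 organelle transcripts were called by edgeR (camera adjusted p = 0.856), at an unadjusted p under 0.05, by DESeq2 and by limma. From 60 to 120 DAF 0 were called by edgeR for flavonols and proanthocyanidins (0.511; unadjusted 2 and 1, DESeq2 1 and 0), laccases (0.593; 1 and 1, 1 and 1), carotenoid cleavage (0.345; 0 and 1, 0 and 1), pollen (0.571; 0 and 0, 0 and 0) and organelle transcripts (0.560; 0 and 0, 0 and 0), also when adjusted over the list alone, and limma on log2(FPKM + 1) called 1 lower for the flavonol and the cleavage list. Members that rose and fell numbered 6 and 3 of 44 for lignin (0.134, 8 and 3 when adjusted over the list alone), 0 and 2 of 25 for abscisic acid signalling (0.699, 0 and 2), 1 and 1 of 24 for ethylene (0.968, 2 and 2), 1 and 2 of 22 for the cuticle (0.243, 1 and 2), 4 and 2 of 46 for sucrose (0.266, 6 and 4) and 5 and 0 of 37 for organic acids (0.0580, 5 and 0). They numbered 0 and 2 of 8 for bromelains (0.511, 1 and 3), 1 and 2 of 34 for senescence (0.713, 1 and 2), 3 and 11 of 79 for the cell cycle (0.1197, 4 and 14), 4 and 8 of 43 for defence (0.379, 6 and 9) and 3 and 2 of 38 for heat shock (0.713, 3 and 3). Too few members were tested for flavonoid transport (0), MYB (2), bHLH (1), secondary wall (1) and seed storage (1) lists. MYB80 Aco000847 went from 5.57 ± 2.91 to 1.05 ± 0.200 FPKM from 90 to 120 DAF (edgeR adjusted p = 0.0286), a call lost without 90 DAF replicate 2 (0.0745) or 3 (0.0508) or any library of 120 DAF (0.0646 to 0.0908, within 8.56e-04 to 0.0908 over all alternatives).

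The light-reaction list stood higher at 90 than at 60 DAF by camera (adjusted p = 1.63e-10; adjusted p = 0.591 with an estimated correlation), and 90 DAF replicate 2 alone is a candidate explanation. Without it the list median was 0.52 (quartiles -0.06 to 1.40, 38 of 53 genes above 0, camera adjusted p = 5.91e-04; adjusted p = 0.586 with an estimated correlation), against a median of 1.82 with it. The median stayed above 0 and the lower quartile did not, which leaves the question open. No biological explanation was tested.

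The sucrose synthase gene Aco006349, the phosphoenolpyruvate carboxylase gene Aco010025 and the starch synthase gene Aco010848 were lower at 90 DAF than at both other ages, unlike another sucrose synthase gene, Aco009508 (238 ± 55.1 FPKM at 90 and 12.1 ± 8.52 at 120 DAF). Harvest at another hour of the day may account for it, since the labels used here give no hour, and in the KEGG pathway Circadian rhythm - plant 5 of 77 genes fell from 60 to 90 DAF (median -0.12, camera adjusted p = 0.0331; adjusted p = 0.852 with an estimated correlation), while from 90 to 120 DAF it did not pass (median 0.18, 0.460). The 9 genes assigned to LHY, a morning clock gene chosen after its values were seen, all had values below 0 from 60 to 90 DAF (median -1.41), and 8 had values above 0 from 90 to 120 DAF (median of the 9 0.83, range -8.31 to 3.54), with Aco009204 (-2.07 ± 0.32, then 1.56 ± 0.31) and Aco011903 (-5.90 ± 0.95, then 3.54 ± 0.86) called both times by edgeR. The exception, Aco001524, stood at 0 to 4.61 FPKM and was not called (-8.31 ± 3.57), and GIGANTEA Aco014347, an evening clock gene chosen likewise, had 2.30 ± 0.47 and then 0.48 ± 0.45, so it did not return. The values of 8 LHY genes turned back, with only Aco009204 and Aco011903 called, and GIGANTEA did not, so an hour of harvest and a change with age cannot be told apart.

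Libraries 120 DAF replicate 2 and 90 DAF replicate 1 each held genes out of step with their age, and RNA of another age mixed in may account for it. In the former Aco011715 stood at 1725 FPKM against 14.5 and 19.4 (29.7% of its earlier level), and of 4 other genes abundant earlier and near absent from the other libraries of 120 DAF, Aco016200 and Aco018386 stood at 0, Aco019529 at 1.38% and Aco000118 at 43.8% (median 0.688%, quartiles 0 to 11.99%). In 90 DAF replicate 1 Aco005343 stood at 290 FPKM against 10.6 and 6.08 (15.5% of its level at 120 DAF). There 17 other genes of ripe peel had a median share of 3.17% (quartiles 1.85 to 7.77%). They were picked for at least 20 FPKM in every library of 120 DAF and a mean under 1% of that level in the other libraries of 90 DAF. The same rule picked separate genes for replicates 2 and 3, with medians of 0.142% (0.0916 to 22.7%, 4 genes) and 0.211% (0.137 to 0.497%, 5 genes). Genes raised in replicate 1 were thereby kept out of those sets, so the 3 medians are not a like comparison. Aco016200 and Aco018386 averaged 78.7 and 76.7 FPKM at 60 and 90 DAF, so a mixture at the 29.7% of Aco011715 would have brought in both. Their values of 0 and the 1.38% of Aco019529 argue against a mixture at that share in 120 DAF replicate 2, for these genes. Aco000118 went the other way. In 90 DAF replicate 1 the shares spread widely and few genes could be used. There a mixture and a peel out of step in its maturation cannot be told apart. Such a peel was not tested for in either library. Aco011715 and Aco005343 were chosen after their values were seen.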
